A study of Rattus norvegicus with 9 samples.

How the data were processed

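RNA of 9 rat kidneys or kidney samples was sequenced as poly(A) libraries in paired-end reads, per the labels' protocols, and the labels gave all libraries batch 1. The labels placed 3 libraries in each of the sham, I/R and I/R + rapamycin groups. They number the replicates and do not say that each came from a separate animal, so p-values measure the spread between these samples. The labels name both kidney tissue and renal tubular cells as the source. The submitters' processing notes name cutadapt, HISAT2, StringTie, DESeq2 and the build Rnor_6.0, with no versions, and the strand setting, the annotation and the counting rule are not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense or overlapping gene are not separable here.

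The authors deposited raw read counts for 30454 Ensembl gene IDs in each library, as whole numbers. They also deposited FPKM values, per the file headers, for 11235 genes, each at 1 FPKM or more in at least 8 of the 9 libraries, with counts identical to those of the count table. Gene symbols come from that FPKM table alone, so 11232 of the 17335 tested genes could be named by it and the rest are given by ID or as a count. Coordinates are not printed, since those listed do not settle the build.

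Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM factors, the default filter on low counts and quasi-likelihood tests with robust dispersion estimates, all 9 libraries in one fit without covariates. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. CPM values use the TMM-scaled library sizes, and standard errors are the log2 fold change divided by the square root of the quasi-likelihood F statistic. The 40 gene lists were fixed before the data were examined, and the 32 with at least 5 tested members were tested with camera on voom values (limma 3.58.1), adjusted over the lists of a comparison. The other 8 had fewer than 5 tested members and no list test. Transcript length was implied by the ratio of counts to FPKM. Libraries of a group were compared for duplicates, and the chi-square of their counts per degree of freedom ranged from 33.7 to 133, so none was counted as a copy of another.

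The genes named were chosen by a rule fixed before the data were examined: per comparison, up to 8 called genes with the largest rise and up to 8 with the largest fall, with a symbol, non-overlapping groups and a mean of at least 5 CPM, 2 to 4 members of each list described with the smallest p, the genes changed in opposite ways, and 17 injury, mTOR, autophagy and apoptosis genes in every case, of which 3 have no symbol in the tables. Some genes that this rule names are not reported here. The other called genes named, LOC100911413, LOC681544, LOC103690996, RT1-S3 and ENSRNOG00000070622, the stress and globin genes given per library, and the genes given as other observations were chosen after their values were seen. The alternatives were DESeq2 1.42.0, DESeq2 and upper-quartile factors in edgeR, no filter or a stricter filter on low counts, a fit of the 6 libraries compared, the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1), stricter thresholds, and each library left out in turn. Removal of the length trend, the genes of the FPKM table alone, and the fit without I/R 1 and sham 3 were added after the data were seen.

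The test was tested on simulated data with the real means, library sizes and dispersions for I/R against sham. Of 16980 simulated genes tested, the test recovered 30% of the 50 changed 1.5-fold, 70% of the 100 changed 2-fold and 98% of the 50 changed 4-fold, with 13 of 147 calls among unchanged genes. The changed genes were drawn from those with a mean count of at least 100, so recovery among genes with fewer reads was not measured. In 20 simulations of unchanged groups a mean of 0.65 genes was called in I/R against sham, 0.3 in I/R + rapamycin against I/R and 0.35 in I/R + rapamycin against sham, with at most 2 in each. With total counts of 44582251 to 60538627 per library, the spread between libraries rather than counting error limited the precision of abundant genes.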

Results

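Poly(A) RNA from rat kidney was sequenced in 9 libraries that fell into 3 groups of 3. The sham group had surgery without ischaemia. The I/R group had 45 min of renal ischaemia followed by reperfusion, a model of acute kidney injury in which blood flow to the kidney is stopped and then restored. The I/R + rapamycin group had the same injury and received rapamycin, a drug that binds FKBP12 and blocks mTOR complex 1, a kinase complex that promotes protein synthesis and restrains autophagy. The labels did not agree on the treatment: the series design gave male rats, intraperitoneal injection and 1 mg/kg per day, and the sample protocols gave both sexes, oral gavage, 1 or 2 mg/kg per day and 3 or 7 days of reperfusion in 6 groups. The dose, route and time of the sequenced kidneys were therefore taken as unsettled. Total counts ranged from 44582251 (I/R + rapamycin 1) to 60538627 (sham 3), and 17335 genes had enough reads to be tested.

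Libraries of the same group differed widely from each other. The first principal component held 26.2% of the variance and set sham 3 and I/R 1 at one end and I/R + rapamycin 1 and I/R + rapamycin 2 at the other. Fos, an immediate early transcription factor gene induced within minutes of stress, was at 512 CPM in sham 3, 200 CPM in sham 2 and 34.4 CPM in sham 1. It was at 260 CPM and 316 CPM in I/R 2 and I/R 3 and at 17.5 CPM in I/R 1, and the rapamycin libraries ranged from 14.1 to 24.5 CPM. The heat shock gene Hspa1b ranged from 54.0 to 856 CPM within the sham group. The globin transcript Hba-a1, a marker of red blood cells, was at 178, 145 and 1513 CPM in the sham libraries, at 736, 1891 and 1869 CPM in the I/R libraries and at 80.7, 51.5 and 301 CPM in the rapamycin libraries.

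**Figure D1:**
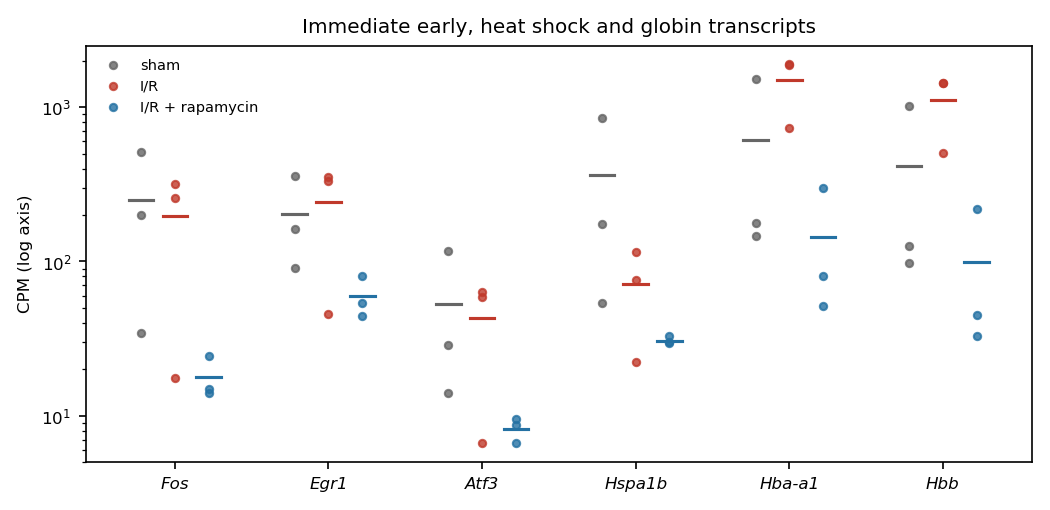
CPM of 4 immediate early and heat shock transcripts and of 2 globin transcripts on a log axis, with 1 point per library and a line at the mean of each group. Fos ranged from 34.4 to 512 CPM in sham, from 17.5 to 316 CPM in I/R and from 14.1 to 24.5 CPM with rapamycin.

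The comparison of I/R with sham asked what the injury changed in the kidney. In injured kidneys 3 genes of the acyl-CoA synthetase medium chain family, which activate medium-chain fatty acids in mitochondria, rose. Acsm3 went from 165 ± 21.0 CPM (SD, n = 3) in sham to 440 ± 72.9 CPM (SD, n = 3) in I/R, Acsm5 from 8.38 ± 1.16 to 26.4 ± 9.61 CPM, and 1 of the 2 listed Acsm2 genes from 23.1 ± 3.02 to 56.5 ± 9.71 CPM. Col15a1, which encodes collagen XV, rose from 7.36 ± 1.46 to 22.8 ± 0.887 CPM, and Lamc3, a laminin chain, from 45.1 ± 2.05 to 77.1 ± 7.10 CPM. Gp2, which encodes a membrane glycoprotein related to uromodulin, fell from 235 ± 55.0 to 64.0 ± 16.7 CPM, and the glutathione transferase Gstm7 fell from 27.4 ± 2.16 to 12.5 ± 2.33 CPM.

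With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 10 of 17335 genes passed an adjusted p of 0.05, 6 higher and 4 lower in I/R. The log2 fold changes of the higher genes with a symbol were 1.66 for Acsm5 (SE 0.23, adjusted p = 0.044), 1.63 for Col15a1 (SE 0.16, adjusted p = 0.0119), 1.42 for Acsm3 (SE 0.17, adjusted p = 0.019), 1.29 for Acsm2 (SE 0.15, adjusted p = 0.019), 1.02 for the serine protease inhibitor gene Serpine2 (SE 0.13, adjusted p = 0.0426) and 0.77 for Lamc3 (SE 0.11, adjusted p = 0.044). The lower genes were Gp2 at -1.88 (SE 0.21, adjusted p = 0.019), Gstm7 at -1.13 (SE 0.15, adjusted p = 0.044), the apolipoprotein L gene Apol11a at -0.88 (SE 0.12, adjusted p = 0.044) and LOC100911413 at -1.25 (SE 0.13, adjusted p = 0.0119). All 10 had 3 values in one group on the same side of the 3 in the other, against 14.6% of all tested genes and the 10% that chance gives. The test selected these genes on the same values, so this is no separate support. The other Acsm2 gene listed had a log2 fold change of -0.07 (adjusted p = 0.926), and the authors' counting could have split reads between such near-identical copies, so the Acsm2 values are uncertain. Acsm2, Acsm3, Acsm5 and Gp2 lie near each other on chromosome 1, and 6 pairs of the called genes lay within 1 Mb. At an unadjusted p of 0.05, 1633 genes passed, 9.42% of those tested. DESeq2 called 234 genes, among them these 10. The count fell to 0 without sham 2 and without I/R 3, to 3 without sham 1 and to 4 without I/R 2, and rose to 36 without I/R 1 and to 16 without sham 3.

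**Figure D2:**
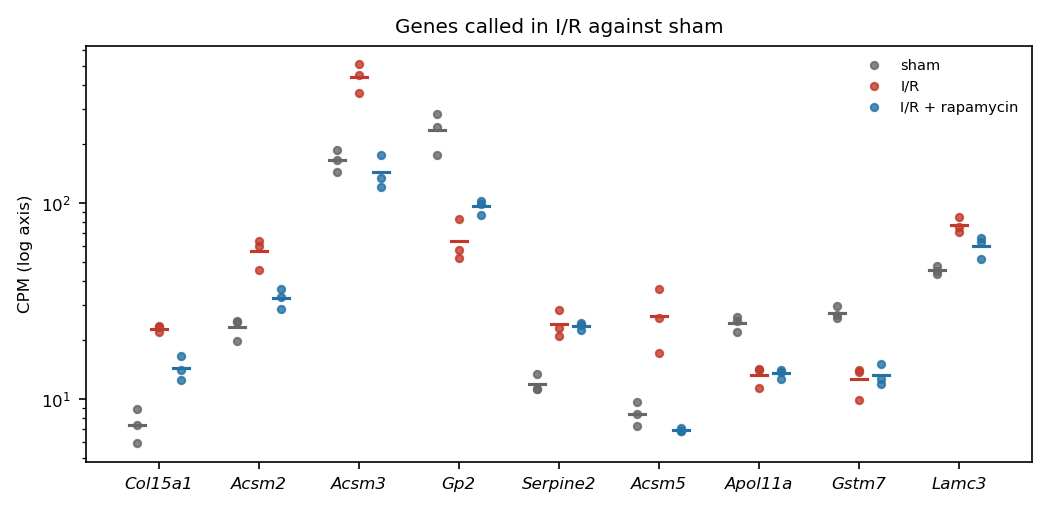
CPM on a log axis of the 9 genes with a symbol that were called in I/R against sham, with 1 point per library and a line at the group mean. Acsm3 and Acsm5 in the rapamycin libraries, at means of 143 and 6.95 CPM, lay near the sham means of 165 and 8.38 CPM.

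The tubular injury markers that could be measured by name did not pass the test. Only genes at 1 FPKM or more in at least 8 of the 9 libraries carry a symbol here. A marker under 1 FPKM in all 3 sham libraries and raised by injury could therefore not be among the 16 measured of 24 listed. Of the 16 measured members of the tubular injury and repair list, edgeR called 0 over all genes and 0 adjusted over the list alone, DESeq2 called 0, and 2 had an unadjusted p under 0.05. Their median log2 fold change was -0.08 and their mean 0.10, and the camera adjusted p was 0.787. Spp1, which encodes osteopontin, was at 129 ± 3.83 CPM in sham and 362 ± 270 CPM in I/R, with a log2 fold change of 1.49 (SE 0.58, adjusted p = 0.501), and its I/R values were 199, 214 and 674 CPM. Lcn2, the gene of the injury marker NGAL, stood at 3.19 ± 1.82 CPM in sham and 2.86 ± 0.949 CPM in I/R (log2 fold change -0.16, SE 0.46). The phosphate transporter Slc34a1 of the proximal tubule and Umod of the loop of Henle had log2 fold changes of 0.05 (SE 0.17) and 0.22 (SE 0.28). Hmox1 was at 0.08 (SE 0.51), Col1a1 at 0.28 (SE 0.49), Bax at -0.08 (SE 0.13) and Bcl2 at 0.04 (SE 0.16), and none of them passed the test. In the same comparison Mtor was at 0.15 (SE 0.095), Fkbp1a at -0.09 (SE 0.098), Map1lc3b at -0.06 (SE 0.10), Sqstm1 at 0.05 (SE 0.11) and Becn1 at -0.04 (SE 0.071). Havcr1, Mki67 and Il1b could not be reported by name, since the tables used do not pair these symbols with an ID.

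By camera with a preset inter-gene correlation of 0.01, 8 of 32 tested gene lists differed between I/R and sham. With a correlation estimated for each list, none of the 8 passed (adjusted p = 0.818 for the collecting duct list, 0.824 for the ribosomal protein, interferon, podocyte and circadian lists and 0.869 for the ribosome biogenesis, sterol and proximal tubule lists), and fry, a rotation test for a shared direction, gave adjusted p values of 0.375 or more for these lists. By camera with the preset correlation, all 35 measured ribosomal protein genes were fitted below 0, with a median log2 fold change of -0.33 (adjusted p = 3.12e-19), and 19 of them were lower adjusted over the list alone. Over all genes edgeR called 0 of them, DESeq2 called 2, and 24 had an unadjusted p under 0.05. Rpl5 was at -0.42 (SE 0.11) and Rps23 at -0.39 (SE 0.11). The ribosome biogenesis list was lower too, with a median of -0.12 (adjusted p = 0.0397), a call that ended with the length trend removed and without I/R 1 and sham 3 (adjusted p = 0.0768 and 0.877, range over alternatives 0.00172 to 0.877). The interferon response list was higher, with a median of 0.45 over 18 members (adjusted p = 3.24e-05), 4 of them higher adjusted over the list alone, and Irf7, a transcription factor of the interferon response, was at 0.94 (SE 0.28, adjusted p = 0.349). Podocyte genes were lower, with a median of -0.25 over 10 members (adjusted p = 0.000252) and 3 lower adjusted over the list alone. Collecting duct genes had a median of -0.28 over 14 members (adjusted p = 0.000252), with the sodium channel subunit gene Scnn1a at -0.30 (SE 0.098).

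Sterol and fatty acid synthesis genes were higher, with a median of 0.21 over 24 members (adjusted p = 0.000862, and adjusted p = 0.869 with an estimated correlation), 4 higher and 1 lower adjusted over the list alone. Among them Mvd was at -0.49 (SE 0.13). Circadian clock genes had a median of 0.27 over 15 members (adjusted p = 0.00127, and adjusted p = 0.824 with an estimated correlation), 2 higher adjusted over the list alone, with the clock gene Per1 at 0.44 (SE 0.13), and proximal tubule genes a median of 0.14 over 27 members (adjusted p = 0.0348, and adjusted p = 0.869 with an estimated correlation), 1 of them, Acsm2, called over all genes. Over all genes edgeR called 0 members of the ribosome biogenesis, interferon, podocyte, collecting duct, sterol and circadian lists, in which 5, 7, 3, 4, 11 and 6 had an unadjusted p under 0.05 and DESeq2 called 0, 1, 1, 0, 2 and 0. Proximal tubule genes lost their call without sham 1 and without I/R 2 (adjusted p = 0.697 and 0.403), and ribosome biogenesis genes without sham 2, sham 3 or I/R 1 (adjusted p = 0.167, 0.448 and 0.295). Across genes, fold changes of I/R against sham rose with the transcript length implied by counts and FPKM (Spearman correlation 0.304 over 11232 genes, which are not independent replicates), and ribosomal protein genes had a median implied length of 1440 against 3200 bases for all genes with one.

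The comparison of I/R + rapamycin with I/R asked what the drug changed in injured kidneys. Acsm3 and Acsm5 fell: Acsm3 from 440 ± 72.9 CPM (SD, n = 3) in I/R to 143 ± 28.5 CPM (SD, n = 3) with rapamycin, and Acsm5 from 26.4 ± 9.61 to 6.95 ± 0.147 CPM. Esm1, an endothelial proteoglycan gene, fell from 18.4 ± 2.65 to 8.91 ± 1.12 CPM, and Gja1, which encodes the gap junction protein connexin 43, from 28.8 ± 4.67 to 13.6 ± 1.63 CPM. The class I histocompatibility gene RT1-T24-4 fell from 59.8 ± 6.10 to 31.6 ± 4.39 CPM. The glutathione transferase Gsta2 rose from 657 ± 97.3 to 1374 ± 208 CPM.

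The edgeR test called 22 genes, 3 higher and 19 lower with rapamycin. Gsta2 had a log2 fold change of 1.06 (SE 0.16, adjusted p = 0.0466), and the other 2 higher genes were LOC681544 at 1.98 (SE 0.30) and LOC103690996 at 0.92 (SE 0.13). The lower genes included Acsm5 at -1.93 (SE 0.23, adjusted p = 0.0339), Acsm3 at -1.62 (SE 0.17, adjusted p = 0.0285), Crispld2 at -1.12 (SE 0.17, adjusted p = 0.043), Gja1 at -1.08 (SE 0.15, adjusted p = 0.0379), Esm1 at -1.05 (SE 0.14, adjusted p = 0.0379), RT1-T24-4 at -0.92 (SE 0.11, adjusted p = 0.0339), Plcxd2 at -0.89 (SE 0.13, adjusted p = 0.0408) and the pseudokinase gene Trib1 at -0.80 (SE 0.11, adjusted p = 0.0372). The class I gene RT1-S3 was at -0.63 (SE 0.094, adjusted p = 0.0408). Class I genes share sequence, so the values of RT1-T24-4 and RT1-S3 are uncertain. Of the 22 genes, 8 have no symbol paired with their ID, and these included ENSRNOG00000070622, at 45.4 CPM in I/R, 48.1 CPM in sham and 0.596 CPM with rapamycin. The largest falls were among these 8, down to a log2 fold change of -9.26 (SE 1.2, adjusted p = 0.0408), from a mean of 1.45 CPM in I/R. Of the 22 genes, 3 were among the 9 IDs near 0 in the rapamycin libraries that are given as other observations. That set takes only IDs under 0.3 CPM, so it leaves out ENSRNOG00000070622, and the count of 3 depends on this limit. All 22 had groups that did not overlap, against 24.6% of all tested genes and 10% by chance, which is no separate support since the test selected them on these values. At an unadjusted p of 0.05, 2817 genes passed, 16.3% of those tested, and DESeq2 called 693 genes, 19 of the 22 among them. The count fell to 0 without I/R + rapamycin 1 and without I/R + rapamycin 2, to 1 without I/R 2 and to 3 without I/R 3, and rose to 47 without I/R 1.

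At the RNA level, the components of the pathway that rapamycin acts on showed no called gene. These RNA values do not measure mTOR kinase activity or the rate of autophagy. Of 33 measured mTOR pathway members, edgeR called 0 over all genes, 2 were higher and 1 lower adjusted over the list alone, DESeq2 called 2 higher and 1 lower, and 11 had an unadjusted p under 0.05. The camera adjusted p of the list was 0.555. Mtor itself was at 73.9 ± 4.08 CPM in I/R and 64.0 ± 3.69 CPM with rapamycin (log2 fold change -0.21, SE 0.095, adjusted p = 0.311), and Fkbp1a, which encodes FKBP12, at 88.7 ± 10.7 and 99.8 ± 3.80 CPM (0.17, SE 0.098). Pdpk1, the kinase that phosphorylates AKT and S6K, was at -0.72 (SE 0.12, adjusted p = 0.059). Of 32 autophagy genes, edgeR called 0 over all genes and 0 adjusted over the list alone, DESeq2 called 0, and 7 had an unadjusted p under 0.05, with 16 fitted above 0 and a camera adjusted p of 0.801. Map1lc3b, the gene of the autophagosome protein LC3B, was at 0.07 (SE 0.10), the autophagy receptor gene Sqstm1 at 0.03 (SE 0.11) and Becn1 at 0.15 (SE 0.071). Of 26 lysosome genes, 1 was higher and 1 lower adjusted over the list alone (camera adjusted p = 0.771). Bax was at 0.29 (SE 0.13), Bcl2 at -0.26 (SE 0.16), Spp1 at -0.11 (SE 0.57), Lcn2 at 0.63 (SE 0.46), Slc34a1 at -0.07 (SE 0.17), Umod at 0.09 (SE 0.28), Hmox1 at -0.30 (SE 0.52) and Col1a1 at -0.40 (SE 0.49), and none of these passed the test.

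By camera, 4 of 32 lists differed between the treated and untreated injured kidneys. With an estimated correlation the adjusted p was 0.848 for all 4 lists, and by fry it was 0.344 or more. With the preset correlation, all 35 ribosomal protein genes were fitted above 0, with a median of 0.26 (adjusted p = 1.73e-10) and Rps2 was at 0.44 (SE 0.15). Of these, edgeR called 0 over all genes and 0 adjusted over the list alone, DESeq2 called 0, and 16 had an unadjusted p under 0.05. Oxidative phosphorylation genes had a median of 0.21, with 31 of 34 fitted above 0 (adjusted p = 5.29e-06), and Uqcrb, a complex III subunit gene, was at 0.36 (SE 0.12). The 13 mitochondrially encoded genes had a median of 0.31, 2 of them higher adjusted over the list alone (adjusted p = 3.46e-05), with Mt-nd6 at 1540 ± 234 CPM in I/R and 2581 ± 525 CPM with rapamycin. The immediate early and heat shock list was lower, with a median of -0.75 over 18 members (adjusted p = 0.0317), and Jun was at -1.92 (SE 0.57, adjusted p = 0.199). The 3 measured globin genes moved the same way, with log2 fold changes of -3.37 for Hba-a1, -3.49 for Hbb and -3.34 for Hba-a3. Each was lower adjusted over the erythrocyte list alone, which had only 4 tested members and no list test. Of these 4, edgeR called 0 over all genes and DESeq2 called 0. Over all genes edgeR called 0 members of the oxidative phosphorylation, mitochondrially encoded and immediate early lists, in which 5, 6 and 5 had an unadjusted p under 0.05 and DESeq2 called 0, 5 and 3. Across genes, fold changes fell with implied transcript length (Spearman correlation -0.483 over 11232 genes), and with this trend removed the oxidative phosphorylation and mitochondrially encoded lists were not called (adjusted p = 0.228, range over alternatives 1.22e-10 to 0.848, and 0.248, range 8.41e-07 to 0.848). The immediate early and heat shock list lost its call without I/R 2, without I/R 3 and without I/R + rapamycin 3 (adjusted p = 0.26, 0.196 and 0.125), and the number of lists called rose from 4 to 10 without I/R 1 and to 7 without I/R + rapamycin 2.

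**Figure D3:**
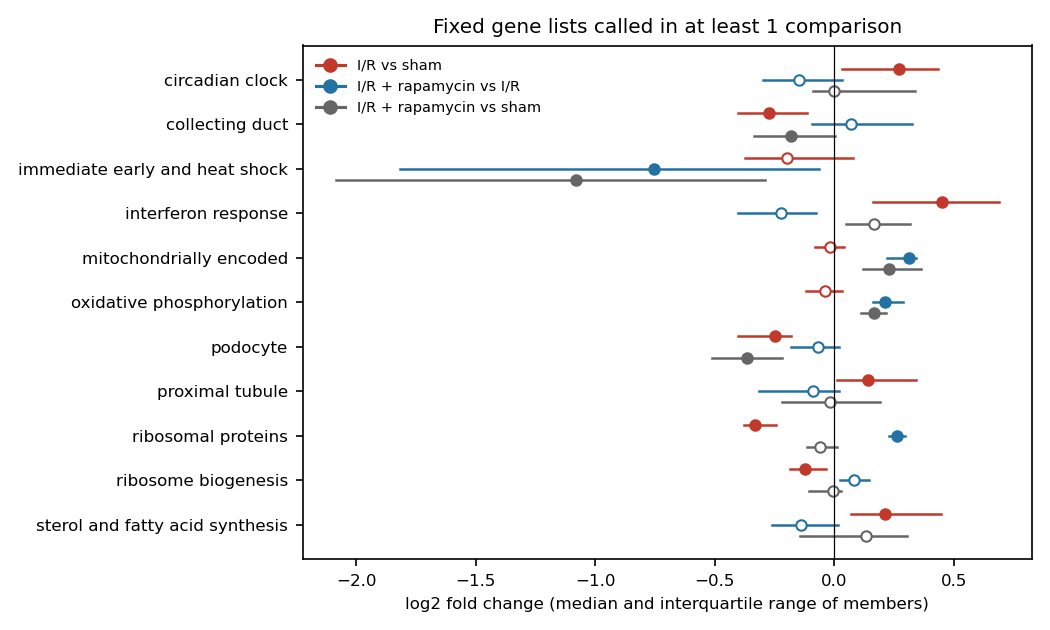
Median log2 fold change (point) and interquartile range (line) of the measured members of each gene list called by camera in at least 1 of the 3 comparisons; filled points have a camera adjusted p under 0.05. Ribosomal protein genes had a median of -0.33 in I/R against sham and 0.26 in I/R + rapamycin against I/R.

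The comparison of I/R + rapamycin with sham asked how far the treated kidneys still lay from uninjured ones. Gpx2, a glutathione peroxidase gene, rose from 2.96 ± 0.0858 CPM (SD, n = 3) in sham to 8.44 ± 1.32 CPM (SD, n = 3), and the methyltransferase gene Inmt from 29.8 ± 2.81 to 64.6 ± 7.00 CPM. Rgn, which encodes the calcium-binding protein regucalcin, rose from 23.8 ± 4.65 to 59.1 ± 5.92 CPM. Smoc1, a matricellular protein gene, fell from 23.5 ± 2.82 to 6.43 ± 1.13 CPM, Esm1 from 24.3 ± 2.30 to 8.91 ± 1.12 CPM and the organic cation transporter gene Slc22a2 from 184 ± 36.5 to 85.0 ± 4.49 CPM. Dusp6, a phosphatase gene induced by ERK signalling, fell from 76.9 ± 9.27 to 38.8 ± 5.10 CPM.

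The edgeR test called 27 genes, 7 higher and 20 lower. Their log2 fold changes included 1.51 for Gpx2 (SE 0.18, adjusted p = 0.0154), 1.31 for Rgn (SE 0.17, adjusted p = 0.0233), 1.12 for Inmt (SE 0.14, adjusted p = 0.0199), -1.87 for Smoc1 (SE 0.19, adjusted p = 0.00711), -1.45 for Esm1 (SE 0.14, adjusted p = 0.00711), -1.11 for Slc22a2 (SE 0.16, adjusted p = 0.0278) and -0.99 for Dusp6 (SE 0.13, adjusted p = 0.0233). Crim1 was at -0.85 (SE 0.12), Frzb, a secreted Wnt antagonist gene, at -0.72 (SE 0.099) and Necab1 at 0.90 (SE 0.13), and all of these passed the test. All 27 had groups that did not overlap, against 19.3% of all tested genes and 10% by chance, which is no separate support since the test selected them on these values. Of the 27 genes, 3 were among the 9 IDs near 0 in the rapamycin libraries, and ENSRNOG00000070622, outside that set, was called too (log2 fold change -6.34, SE 0.55, adjusted p = 0.0132). At an unadjusted p of 0.05, 2394 genes passed, 13.8% of those tested, and DESeq2 called 568 genes, the 27 among them. The count fell to 3 without I/R + rapamycin 1, to 5 without sham 2 and without I/R + rapamycin 2 and to 10 without sham 1. Smoc1 and Esm1 passed the test in all 18 alternatives run for them.

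By camera, 5 of 32 lists differed between treated and sham kidneys. With an estimated correlation all 5 had an adjusted p of 0.917, and by fry 0.382 or more. Podocyte genes were lower, with a median of -0.36 over 10 members and 5 lower adjusted over the list alone (adjusted p = 9.5e-05). Collecting duct genes had a median of -0.18 (adjusted p = 0.0484), with Scnn1a at -0.36 (SE 0.099). Immediate early and heat shock genes had a median of -1.08 (adjusted p = 0.000244), with Jun at -2.19 (SE 0.58). Mitochondrially encoded genes had a median of 0.23 with 4 higher adjusted over the list alone (adjusted p = 9.5e-05), and oxidative phosphorylation genes a median of 0.17 (adjusted p = 0.000216). Over all genes edgeR called 0 members of the podocyte, collecting duct, immediate early, mitochondrially encoded and oxidative phosphorylation lists, in which 5, 5, 8, 5 and 4 had an unadjusted p under 0.05 and DESeq2 called 2, 2, 5, 3 and 0. The number of lists called was 8 without sham 3 and 8 without I/R + rapamycin 3, the collecting duct list lost its call without sham 2, sham 3 or I/R + rapamycin 2 (adjusted p = 0.0936, 0.0516 and 0.32), and the oxidative phosphorylation list without sham 1 (adjusted p = 0.0533). With the replicate number as a block, the collecting duct list also lost its call (camera adjusted p = 0.0539). The mTOR, autophagy and tubular injury lists had camera adjusted p values of 0.321, 0.938 and 0.515. Mtor was at -0.05 (SE 0.095), Fkbp1a at 0.08 (SE 0.098), Map1lc3b at 0.01 (SE 0.10), Sqstm1 at 0.08 (SE 0.11), Becn1 at 0.11 (SE 0.071), Spp1 at 1.39 (SE 0.58, adjusted p = 0.359), Lcn2 at 0.47 (SE 0.46), Slc34a1 at -0.02 (SE 0.17), Umod at 0.31 (SE 0.28), Hmox1 at -0.22 (SE 0.52), Col1a1 at -0.12 (SE 0.49), Bax at 0.21 (SE 0.13) and Bcl2 at -0.23 (SE 0.16), none past the threshold.

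The last comparison asked which genes changed by the injury changed the opposite way with rapamycin. Acsm3 and Acsm5 did: they were higher in I/R than in sham, lower with rapamycin than in I/R, and in treated kidneys their log2 fold changes from sham were -0.20 (adjusted p = 0.634) and -0.27 (adjusted p = 0.65). Of the other genes changed by I/R, Serpine2, Gstm7, Apol11a and LOC100911413 were also called the same way between treated and sham kidneys, with Serpine2 at 1.02 in I/R and 0.99 in treated kidneys and Gstm7 at -1.13 and -1.06. Acsm2, Lamc3 and Col15a1 had log2 fold changes of 0.49, 0.42 and 0.96 in treated kidneys against sham, and Gp2 was at 95.7 CPM there against 235 CPM in sham (adjusted p = 0.0579). None of these 4 passed the test in that comparison.

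Both comparisons hold the I/R libraries, so chance values in them run in opposite directions. Against the 2 genes changed in opposite ways and 0 changed the same way, 20 simulations of unchanged groups gave a mean of 0.1 and at most 1 in opposite ways, and independent lists of these sizes would share 0.0073. The fold changes of the 2 comparisons had a correlation of -0.39 across 17335 genes, against -0.49 in the simulations, and a covariance of -0.158 against -0.12. For I/R and I/R + rapamycin, each against sham, 4 genes were called the same way, against a simulated mean of 0.1, at most 1 and 0.007 for independent lists, the correlation was 0.50 against 0.50 in the simulations, and the covariance was 0.218 against 0.121. With 3 libraries per group the shared libraries could not be split, so part of the overlap counts could come from them. Of 100 groupings of the 9 libraries, 8 gave 2 or more genes changed in opposite ways, the real one included. The count of 2 fell to 1 without sham 3, with 1 of the 2 genes kept, and to 1 without I/R 2, with 0 of the 2 kept. It fell to 0 without any 1 of sham 1, sham 2, I/R 3, I/R + rapamycin 1 and I/R + rapamycin 2, and rose to 13 without I/R 1. Without I/R + rapamycin 3 it stayed at 2, with 1 of the original 2 genes kept.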

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

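All alternatives were planned before the data were examined except the length offset, the FPKM-table genes and the fit without I/R 1 and sham 3. None of the 8775 alternative values of named genes changed the sign of a call, where a sign change counted only if either value was called. The 32 called values of named genes passed in 383 of 576 alternatives; all 32 passed under DESeq2, upper-quartile factors and both filters, and 31 with DESeq2 factors in edgeR. With the FPKM pseudocounts 27 of 32 passed, and with the 6 libraries compared 13. Leaving out 1 library kept from 2 calls, with 21 lost (without sham 2 and without I/R + rapamycin 1) or 16 lost (without I/R 2 and without I/R 3), to 16 with 2 lost (without I/R 1). The cause was not tested for any change below, except that fewer libraries leave fewer degrees of freedom. For I/R against sham the 10 calls became 234 with DESeq2, 2 with the 6 libraries, 18 and 16 with limma on log2(FPKM + 1) and log2(FPKM + 0.1), 26 with the length offset, 67 without I/R 1 and sham 3, and 0 at an adjusted p of 0.01 (1633 genes at an unadjusted p of 0.05 in edgeR). Leaving out 1 library gave 0 to 36. For I/R + rapamycin against I/R the 22 calls became 693 with DESeq2, 6 with the 6 libraries, 14 and 13 with limma, 128 without I/R 1 and sham 3, 0 at 0.01 (2817 at an unadjusted p of 0.05), and 0 to 47 without 1 library. For I/R + rapamycin against sham the 27 calls became 568 with DESeq2, 15 with limma at both pseudocounts, 17 with a fold of at least 2 as well, 4 at 0.01, 104 without I/R 1 and sham 3, and 3 to 40 without 1 library. The 2 genes changed in opposite ways became 46 with DESeq2, 0 with the 6 libraries and at 0.01, 22 without I/R 1 and sham 3, and 0 to 13 without 1 library.

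List calls fell from 8, 4 and 5 to 0 in every comparison with an estimated correlation and with fry. They were 14, 11 and 10 without I/R 1 and sham 3, and without 1 library they ranged from 8 to 11, 3 to 10 and 5 to 8. Replicate numbers gave little sign of pairing: the 9 correlations of same-numbered deviations ranged from -0.213 to 0.136, 2 of them over 0.1. Libraries of different numbers were not compared for reference, so pairing by replicate number was not excluded. With the number as a block 4 of the 32 called values passed and 28 did not, the calls were 1, 1 and 7, the genes changed in opposite ways 0, and the lists called 8, 5 and 6. Genes under the filter on low counts were not tested. In simulated data at this depth 30% of changes of 1.5-fold in I/R against sham were detected, among the more abundant genes from which the changed ones were drawn.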

Other observations

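Tests of the length trend, of the sex of the animals, of the Acsm region and of reads shared between Acsm copies were chosen only after the result was seen. The rule for gene IDs near 0 in some libraries was also set after the pattern was seen.

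Some transporter and enzyme genes, chosen after their values were seen, differed between libraries of the same group. Slc7a13, an amino acid transporter gene, was at 253 to 539 CPM in sham, 271 to 1310 CPM in I/R and 393 to 1260 CPM with rapamycin. Slc7a13, Slc22a7, Cyp4b1 and Slc22a12 all had their 3 highest values in I/R 3, I/R + rapamycin 1 and I/R + rapamycin 2, and Slc22a12, a urate transporter gene, ranged from 88.2 CPM (I/R + rapamycin 3) to 329 CPM (I/R 3). Akr1b7 ranged from 0.615 CPM (sham 3) to 159 CPM (I/R 3).

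Markers of cells present in small numbers were measured for few genes, since only genes at 1 FPKM or more in at least 8 of the 9 libraries carry a symbol. In I/R against sham the neutrophil gene Mmp9 had a log2 fold change of 1.73 (SE 0.57, adjusted p = 0.423 by edgeR) and Jchain, an antibody-secreting cell gene, -1.63 (SE 0.56, adjusted p = 0.439). Macrophage, endothelium and complement lists were not called by camera, with adjusted p values of 0.386, 0.507 and 0.461 in I/R against sham. Without sham 3 the macrophage list was higher in I/R (adjusted p = 1.99e-05, range over alternatives 1.99e-05 to 0.911), and without sham 1 the complement list was lower (adjusted p = 0.0164, range 0.0164 to 0.869).

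Each comparison of 6 libraries has 10 splits, too few for a share under 0.05. The real splits called 10, 22 and 27 genes and the highest other splits 4, 2 and 1, and 1 of 10 splits, the real one, called as many each time. For lists the real splits called 8, 4 and 5, the highest other splits 18, 12 and 16, and 8, 9 and 9 of 10 splits called as many. The split with 18 lists set sham 1, sham 2 and I/R 1 against sham 3, I/R 2 and I/R 3, by camera with the preset correlation. For the ribosomal protein list in I/R against sham the estimated correlation between genes was 0.76, against the preset 0.01. With estimated correlations no list was called in the real groups. The other splits were not run with them, so sample structure and correlation between genes cannot be told apart for the 18 lists. As most splits called as many lists as the real ones, chance was not excluded for the list calls. For genes changed in opposite ways, 8 of 100 groupings of the 9 libraries gave 2 or more and the highest other gave 7, so chance was not excluded for that count.

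With the length trend of each library removed, ribosomal protein genes stayed lower in I/R than in sham by camera with the preset correlation (adjusted p = 4.07e-14, range over alternatives 2.36e-22 to 0.824). Their median over the genes with an FPKM value was -0.32 before and -0.20 after (SD 0.11 and 0.12), so the fitted trend took up part of it and not all. With an estimated correlation camera did not call this list even before the removal (adjusted p = 0.824). The p-value after removal therefore cannot decide whether the trend is the whole cause. In I/R + rapamycin against I/R the same list kept an adjusted p of 0.0312 (range 4.41e-14 to 0.848) while its median went from 0.24 to 0.06 (SD 0.082 and 0.12), so the trend and the group cannot be told apart for it. The oxidative phosphorylation median went from 0.19 to 0.03 (SD 0.15 and 0.13, adjusted p = 0.228, range 1.22e-10 to 0.848) and the mitochondrially encoded median from 0.29 to 0.05 (SD 0.22 and 0.21, adjusted p = 0.248, range 8.41e-07 to 0.848), so the trend is a candidate explanation of both calls, which ended because the medians shrank. In I/R + rapamycin against sham the oxidative phosphorylation and mitochondrially encoded lists stayed higher with the trend removed (adjusted p = 0.00446, range 1.21e-08 to 0.917, and 0.00687, range 4.56e-06 to 0.917), and the ribosomal protein list, not called before at an adjusted p of 0.237, was lower (adjusted p = 9.45e-05, range 9.45e-05 to 0.917). Rapamycin itself stays open as an explanation, since the trend differs with the group.

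A set of 50 gene IDs was near 0 (under 0.3 CPM) in sham 3 and I/R 1 and present in the other 7 libraries, against at most 6 for the other 35 pairs, and 9 IDs were near 0 in the 3 rapamycin libraries and present in the other 6, against at most 4 for the other 83 sets of 3. For the first set, 6 of 48 testis markers were measured, the most abundant being Ift57 at 24.3 CPM, with a median log2 ratio of 0.25 at percentile 95 of random lists; testis RNA and other sources cannot be told apart with so few markers. Only 2 IDs, without a symbol, were present in sham 3 and I/R 1 alone, and the X-linked gene Kdm6a was 1.18 times as high there as in the other 7, at 58.7 and 59.8 CPM against 56.5, 48.1, 56.2 and 58.6 CPM in sham 1, sham 2, I/R 2 and I/R 3 and 39.9 to 50.4 CPM with rapamycin, so the sex of the animals was neither shown nor excluded as a source. For the second set, 11 of 21 adrenal markers had a symbol and were tested, with a median log2 ratio of 0.17 at percentile 99. A symbol was found for 0 of the 9 IDs, so markers with that pattern were left out too and the percentile cannot decide. The most abundant of the 11 markers were Cyb5a at 256 CPM and Por at 209 CPM, with ratios of -0.26 and 0.01. All 11 passed the expression filter in kidney. Among them Akr1b7 was at 0.615 CPM in sham 3, 159 CPM in I/R 3 and 51.2 CPM in I/R + rapamycin 1. The 9 IDs summed to 72.8, 26.8 and 0.785 CPM there, so Akr1b7 did not follow them. These values go against adrenal RNA for this 1 marker, which does not decide for the other markers. Adrenal RNA in the sham and I/R libraries was neither shown nor excluded as a source of the second set, and an untested effect of rapamycin stays open.

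Acsm genes and Gp2 called in I/R against sham lie close together: 6 pairs of called genes lay within 1 Mb, against a median of 0 and at most 3 in 10000 random draws. A difference of this region of chromosome 1 between the animals is a candidate explanation, and a shared response to the injury stays open. For Acsm2, reads shared between its 2 listed copies and a rise of the called copy cannot be told apart. The test pooled the called Acsm genes, which gained 327 CPM while the other Acsm2 gene changed by -65.7 CPM (SE 181). Most of that gain was in Acsm3, which went from 165 to 440 CPM, against 23.1 to 56.5 CPM for the called Acsm2 gene. The pooled test therefore gives no verdict on Acsm3 or Acsm5 singly.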
